A study of Mus musculus with 8 samples.

How the data were processed

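Total RNA from mouse skeletal muscle was labelled with Cy3 and hybridised to 8 1-colour Agilent microarrays with probes for mouse miRNAs. Per the labels' protocols, 100 ng of RNA was used per array. Per the file headers, all 8 arrays lay on 1 slide, were scanned in 1 scan and were read with Feature Extraction 10.5, and the probe design names the mm9 build. The deposited values are spot intensities. Per the file headers, the processed intensity of a spot is its signal after subtraction of a spatially detrended background, with no normalization between arrays, and the files also hold raw median intensities and a total intensity per miRNA made by the scanner software. Each deposited spot or miRNA also carries flags of 0 or 1, per the file headers, for outlier spots, saturation and detection. The labels give no normalization or test of the submitters.

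Groups were taken from the titles, which name 4 control and 4 diabetic arrays, and from the description and the group entry, which name the same groups. The strain entry of each sample contradicts them: it gives db/db for control and db+ for diabetic samples, opposite to the design text, in which db/db mice are diabetic. Directions below are therefore diabetic minus control by title, description and group entry. The 4 control arrays lay in slide row 1 and the 4 diabetic arrays in slide row 2, so 0 rows held both groups and the effects of row and group cannot be told apart. Replicate numbers match slide columns.

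Each array held 12493 spots, of which 953 control spots and 200 spots of 10 viral miRNAs were left out of the tests. The other 11340 spots belonged to 1672 probes of 567 mouse miRNAs, with 1 to 4 probes per miRNA and 5 to 20 spots per probe. Outlier spots were dropped and the processed intensities of the remaining spots of a probe were averaged. A probe counted as detected on an array where at least 50% of these spots were well above background. Because 12.4% of the probe values were detected, each array was divided by its 75th percentile over the 152 probes detected on all 8 arrays. The scaled probes of a miRNA were averaged on the linear scale, raised to a floor of 0.0162 (the 1st percentile of detected miRNA levels, −5.95 on the log2 scale) and converted to log2. A miRNA counted as detected if any of its probes was. The 126 miRNAs detected on at least 4 of the 8 arrays were tested, whatever the group; 24 of their 1008 values lay at the floor. miRNAs under this minimum, including miR-135a, which was detected on 0 arrays, have no test.

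Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the single term), and p-values were adjusted by the Benjamini-Hochberg method over the 126 miRNAs, with a threshold of 0.05. A log2 difference has a standard error from the moderated variance and a 95% interval. Of 17 miRNA lists fixed before the data were examined, the 12 with at least 3 tested members were compared with the other tested miRNAs by camera (two-sided, preset correlation 0.01), with camera at an estimated correlation and with fry beside it. A miRNA joined a list through the name of its hairpin, and both arms counted. The insulin and glucose metabolism list contains the 4 tested members of the miR-29 family, so the 2 lists are not independent. Numbers of detected miRNAs and brightness (log2 of the 75th percentile) were compared with two-sided exact permutation tests over 70 assignments, whose smallest possible p is 0.0286. Figures were drawn with matplotlib 3.10.9. Hairpin gene names and their neighbours came from a gene table of assembly GRCm38.p6, not the build of the array, so no coordinates are given; 110 of the 126 tested miRNAs matched a hairpin gene.

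The miRNAs named in the text were chosen by a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among miRNAs past the threshold whose groups did not overlap, filled to 5 per direction by the smallest p where fewer pass. It adds every tested muscle-specific miRNA, every tested member of the miR-29 family and miR-135a, and the 2 members with the smallest p of each other list with at least 3 tested members. The limma step was tested on simulated data with the 126 miRNAs, 12 of them changed, in 50 simulations of the comparison of diabetic with control arrays. It recovered 1.7% of changes of 0.5 on the log2 scale, 59.7% of changes of 1 and 94.5% of changes of 2, and made 0.08 calls per simulation with no change. Of the calls, 9.1% were false with changes of 0.5, 6.3% with changes of 1 and 6.4% with changes of 2. The simulated miRNAs were independent and had the same SD in both groups. The real miRNAs are correlated and vary more on the control arrays, so these shares need not hold for the real arrays.

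The alternatives planned before the data were examined covered the scaling (percentile over all mouse probes, median of the detected probes, quantile normalization, no scaling), normexp background correction, the summary over probes, the filter, the floor, the variance model, array weights, the replicate number as a block, the detection rule, the correlation in camera and leaving out each array. The planned normexp correction on mean intensities was run on median intensities, because the files hold no mean intensity. It adds an offset of 50 to every spot, which by itself shrinks the log2 differences of dim miRNAs. A block by slide was not run, since there is 1 slide. Chosen after seeing the data were the removal of control 2 and diabetic 4 together (the brightest and the dimmest array) and the detection call of the scanner software. The number of arrays limits the precision of every value.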

Results

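miRNA levels were measured in skeletal muscle of the C57BL/KsJ db/db mouse, a strain that lacks a working leptin receptor and becomes obese and diabetic, and of db+ control mice. There were 4 arrays per group, and each array gave levels for 567 mouse miRNAs, of which 126 were detected on enough arrays to be tested. The number of miRNAs detected was 129 ± 15.3 on the control arrays and 121 ± 13.1 on the diabetic arrays (SD, n = 4; two-sided exact permutation p = 0.457). Array brightness, the log2 of the 75th percentile of intensity, was 8.57 ± 0.47 on the control arrays and 8.46 ± 0.49 on the diabetic arrays (SD, n = 4; two-sided exact permutation p = 0.8). Both differences depended on single arrays. The difference in detected miRNAs, −7.75, was −1.75 without control 4 and −1.33 without diabetic 4. That in brightness, −0.11, was 0.13 without control 2 and 0.12 without diabetic 4. No spot of a mouse miRNA was saturated.

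The comparison of the groups asks which miRNAs of skeletal muscle differ between diabetic and control mice. In the arrays labelled diabetic, 6 miRNAs were higher, and 3 of them came from the miR-29 family, whose targets include the mRNAs of collagens and other matrix proteins. The direction rests on the titles, descriptions and group entries, because the strain entries name the opposite genotypes. miR-29c was 2.38-fold higher, with a relative log2 level of 0.22 ± 0.27 on the control arrays and 1.47 ± 0.07 on the diabetic arrays (SD, n = 4; limma log2 difference 1.25, SE 0.20, adjusted p = 0.00642). The other strand of its hairpin, miR-29c*, was 2.26-fold higher (log2 difference 1.17, SE 0.20, limma adjusted p = 0.00642). With normexp background correction its log2 difference was 0.38 and it did not pass (limma adjusted p = 0.939). The offset in that setting shrinks the differences of dim miRNAs such as miR-29c*, so its effect cannot be told apart from that of the background correction. miR-29b was 1.98-fold higher, from −0.77 ± 0.37 to 0.22 ± 0.04 (SD, n = 4; log2 difference 0.99, SE 0.22, limma adjusted p = 0.0283). The fourth tested member, miR-29a, had a log2 difference of 0.76 (SE 0.21) and did not pass (limma adjusted p = 0.0581); it passed in 8 of 23 alternatives, and under quantile normalization it had the same rank on every array and its difference was 0. In the GRCm38.p6 gene table, Mir29c neighbours Mir29b-2, and Mir29a neighbours Mir29b-1.

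The other 3 miRNAs that passed were miR-193, miR-101b and miR-101a. miR-193 was 2.24-fold higher on the diabetic arrays, from −2.05 ± 0.49 to −0.89 ± 0.15 (SD, n = 4; log2 difference 1.16, SE 0.26, limma adjusted p = 0.0283). miR-101a, a repressor of the histone methyltransferase Ezh2, was 2.04-fold higher (log2 difference 1.03, SE 0.25, limma adjusted p = 0.0368). miR-101b had a log2 difference of 1.12 (SE 0.27, limma adjusted p = 0.0368), but it was detected on 1 of 4 control and 3 of 4 diabetic arrays and had 1 value at the floor, so its size is uncertain. With normexp its difference was 0.25 (limma adjusted p = 0.998), and miR-101a did not pass either. miR-101b passed in 10 of 22 alternatives and miR-101a in 11 of 23. Whether the probes of miR-101b also bind miR-101a was not tested. On the control arrays miR-101a was brighter, with a mean level of −2.39 against −5.53, so their calls need not be separate findings. For each of the 6, all 4 diabetic arrays lay above all 4 control arrays. Such a separation was found for 11 of the 126 tested miRNAs, in either direction, where chance gives 2.86% per miRNA.

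**Figure D1:**
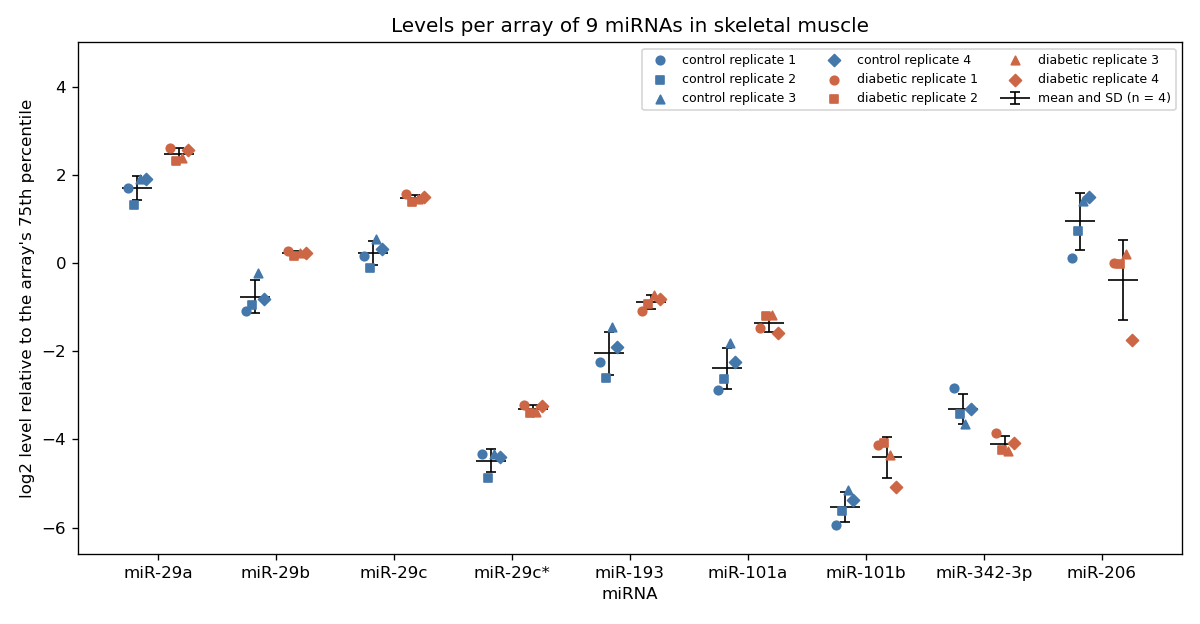
Relative log2 levels of 9 miRNAs on each array; blue points are control arrays, orange points diabetic arrays, the marker shape is the replicate number, and black bars are the mean and SD (n = 4). For miR-29c the mean is 0.22 on the control arrays and 1.47 on the diabetic arrays; for miR-206 diabetic 4 lies at −1.75, below the other 3 diabetic arrays.

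No miRNA passed the threshold in the lower direction with limma, although 13 had a lower value and 8 a higher value at an unadjusted p under 0.05, where 6.3 of 126 are expected by chance in total. The smallest p in this direction belonged to miR-342-3p, with a log2 difference of −0.80 (SE 0.23, limma adjusted p = 0.0611) and all 4 diabetic arrays below all 4 control arrays. It passed in 7 of 23 alternatives, and with normexp its difference was −0.20. miR-801 had a log2 difference of −2.17 (SE 0.63, limma adjusted p = 0.0663) and passed in 6 of 22 alternatives, with differences from −2.65 to −0.72. It was detected on 3 of 4 diabetic arrays and had 1 value at the floor, so its size is uncertain. The muscle-specific miR-206, known for its rise during muscle regeneration, had a log2 difference of −1.33 (SE 0.44, limma adjusted p = 0.132). Without diabetic 4 its difference was −0.87, and it passed in 3 of 23 alternatives, which were normexp, the filter for detection on all 8 arrays and the replicate block. Those of miR-410 and miR-299* were −1.18 (limma adjusted p = 0.168) and −1.001 (limma adjusted p = 0.237). Without control 4 the difference of miR-410 was −0.78. Over all 126 tested miRNAs the median log2 difference was −0.06.

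The call counts changed when single arrays were left out and with the scaling. Without control 1, control 2, diabetic 1, diabetic 2 or diabetic 3 in turn, 2 miRNAs were higher and 0 lower, and the 2 were miR-29c and miR-29c* each time. Without diabetic 4 the counts were 3 and 1, without control 3 they were 7 and 3, and without control 2 and diabetic 4 together they were 3 and 0. A lost call need not mean that the difference rested on that array, since each such fit also has fewer arrays. Without any 1 of the diabetic arrays miR-29b lost its call, but its log2 difference was 0.97 to 1.01, against 0.99 with all 8. Without control 1 and control 2, where it also lost its call, the difference was 0.88 and 0.93. The higher and lower calls were 8 and 1 with the percentile taken over all mouse probes, 5 and 2 with quantile normalization, 5 and 2 with the median of the detected probes, and 0 and 0 without scaling. The percentile over all mouse probes moved the median log2 difference of all tested miRNAs from −0.06 to 0.26, and quantile normalization moved it to 0.07.

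**Figure D2:**
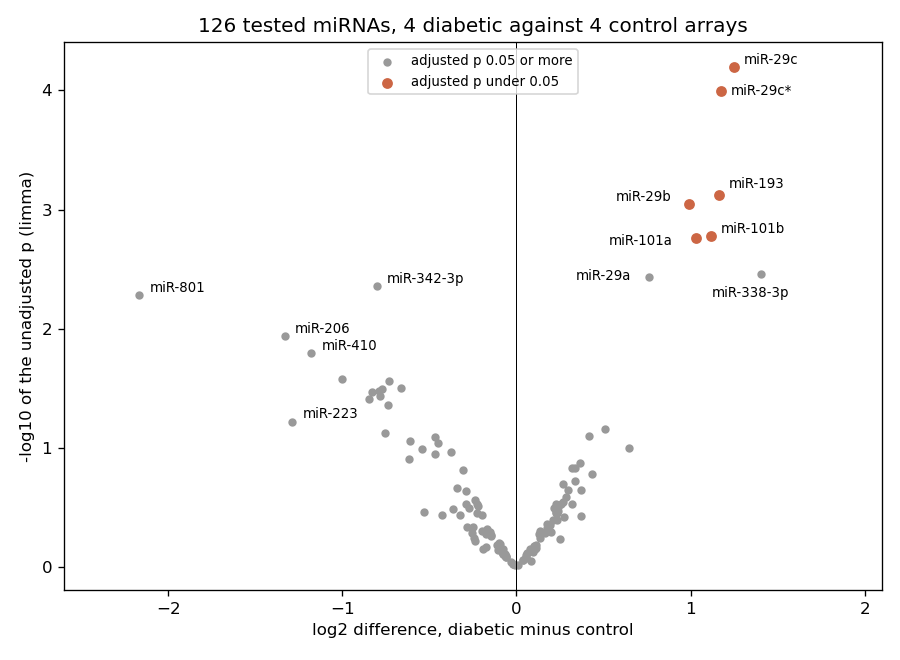
Log2 difference (diabetic minus control) of 126 tested miRNAs against −log10 of the unadjusted limma p; orange points passed an adjusted p of 0.05, grey points did not. The 6 orange points, miR-29c, miR-29c*, miR-29b, miR-193, miR-101a and miR-101b, all lie on the right.

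Of the miRNA lists, the miR-29 family stood apart. All 4 of its tested members had positive log2 differences, from 0.76 to 1.25 with a mean of 1.04, and 3 passed over all miRNAs tested while 4 passed when adjusted over the list alone. Camera gave this list an adjusted p of 1.19e-06 with the preset correlation and an adjusted p of 0.204 (unadjusted p = 0.017) with an estimated correlation. Fry, which tests whether members move one way, gave an adjusted p of 0.00307. The mean level of the family per array was −0.83 ± 0.26 on the control arrays and 0.21 ± 0.09 on the diabetic arrays (SD, n = 4). The two-sided exact permutation p was 0.0286, the smallest possible, and was not adjusted over the 12 lists.

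Among the muscle-specific miRNAs and miR-486, which is enriched in muscle, 0 of 7 tested members passed. The log2 difference was 0.34 (SE 0.22) for miR-1, 0.09 (SE 0.28) for miR-133a, 0.51 (SE 0.25) for miR-133a*, 0.11 (SE 0.27) for miR-133b, −0.53 (SE 0.54) for miR-208b and −0.02 (SE 0.28) for miR-486. miR-206, whose gene neighbours Mir133b in the GRCm38.p6 gene table, is given above. The list's mean log2 difference was −0.12, its median 0.09 and the direction of camera upward, so the signs differed (camera adjusted p = 0.906). The mean was −0.25 without control 2, −4.08e-06 without control 4 and 0.19 with the percentile over all mouse probes. The 95% interval of miR-1 ran from −0.14 to 0.82 and that of miR-133a from −0.53 to 0.72. These differences depended on single arrays, and the signs of those near 0 also on the scaling. Without control 2 the differences were 0.17 for miR-1, 0.28 for miR-133a*, −0.15 for miR-133a and −0.12 for miR-133b, and the last 2 were also negative without diabetic 4 and with quantile normalization. miR-208b was detected on 2 of 4 arrays in each group and had 3 of 8 values at the floor. Its difference, of uncertain size for that reason, ran from −0.98 without control 1 to −0.17 without control 4. That of miR-486 was 0.22 without control 1, and also positive without diabetic 1, without diabetic 2 and with the percentile over all mouse probes.

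The imprinted Dlk1-Dio3 cluster, a large group of miRNA genes expressed from 1 parental chromosome, had lower values on the diabetic arrays in 9 of 10 tested members, with a mean log2 difference of −0.58, and 0 members passed, both over all miRNAs tested and adjusted over the list alone. Camera gave an adjusted p of 0.00961 with the preset correlation, and an adjusted p of 0.77 with an estimated correlation. Fry gave an adjusted p of 0.411. The mean level of the list was −3.94 on control 1 and −3.49 on control 4. On control 2 and control 3 it was −4.89 and −4.61, within the range of the diabetic arrays, −5.19 to −4.59 (two-sided exact permutation p = 0.229 between the groups). The call ended without diabetic 4 (mean −0.45, camera adjusted p = 0.0728), with quantile normalization and with normexp. Without control 4 the mean was −0.33 (camera adjusted p = 0.0364). The members with the smallest p were miR-410 and miR-299*, given above.

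Among lists of other cell types, 3 leukocyte miRNAs had negative log2 differences and 0 of 3 passed over all miRNAs tested; 1 passed when adjusted over the list alone. They were miR-223, abundant in myeloid cells, at −1.29 (SE 0.62, limma adjusted p = 0.344) and at −0.70 without control 2, miR-342-3p, given above, and miR-155, at −0.20, at −0.36 without control 2 and at 0.12 with the percentile over all mouse probes. The list's mean was −0.76 (camera adjusted p = 0.0943 with the preset correlation and 0.359 with an estimated one; fry adjusted p = 0.0316). Without control 4 its mean was −0.83 and it passed (camera adjusted p = 0.0424). The 3 erythroid miRNAs had a mean of −0.15 (camera adjusted p = 0.906), with miR-451 of red blood cells at −0.33 (SE 0.35) and miR-16 at −0.10 (SE 0.20). Without control 2 they were −0.048 and −0.020 and the list mean −0.072, and without diabetic 2 the list mean was −0.038. The stromal list had a mean of −0.31 (camera adjusted p = 0.224), with miR-199a-5p at −0.66 (SE 0.27, limma adjusted p = 0.237) and miR-199b at −0.45 (SE 0.24). Its mean was −0.20 without control 1 and −0.20 without control 4. The mean level of the stromal list was −1.61 on control 1 and −1.59 on control 4, but −2.21 on control 2 and −2.25 on control 3. On the diabetic arrays it was −2.23 to −2.20 (two-sided exact permutation p = 0.343 between the groups). With the percentile over all mouse probes the stromal mean was 0.016 and the erythroid mean 0.18. The adipocyte list had a mean of 0.03, a median of −0.03 and an upward camera direction (camera adjusted p = 0.906), with miR-107 at −0.37 (SE 0.22) and miR-365 at 0.37 (SE 0.29). miR-365 was at 0.13 without control 2, and miR-107 passed in 2 of 23 alternatives.

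Of 15 tested miRNAs linked to insulin and glucose metabolism, 3 rose, all of them of the miR-29 family, and 4 rose when adjusted over the list alone (list mean 0.16, camera adjusted p = 0.125). Without control 2 this list passed, with a mean of 0.12 (camera adjusted p = 0.0387). In the lists of the let-7 family, the miR-30 family, the miR-17 cluster with its paralogues and the miR-23 clusters, 0 members passed. The let-7 list had a mean of −0.06 (camera adjusted p = 0.906), with let-7e at −0.47 (SE 0.27) and let-7b at −0.20 (SE 0.28). The miR-30 list had a mean of 0.18 (camera adjusted p = 0.224), or 0.015 without control 2, with miR-30a at 0.36 (SE 0.23) and miR-30c at 0.29 (SE 0.24). The list of the miR-17 cluster and its paralogues had a mean of 0.02 (camera adjusted p = 0.906), with miR-93 at −0.36 (SE 0.36) and miR-92a at 0.17 (SE 0.25). Without control 2 its mean was 0.22 and it passed (camera adjusted p = 0.0217). The list of the miR-23 clusters had a mean of 0.08 (camera adjusted p = 0.906), with miR-24-1* at 0.65 (SE 0.36) and miR-24 at −0.22 (SE 0.20). Several of these member values moved when 1 array was left out. Without control 2, miR-30a was at 0.19, miR-30c at 0.10, miR-93 at −0.071, miR-92a at 0.31, miR-24 at −0.35 and let-7b at −0.41. Other alternatives moved them the other way. Over all alternatives miR-30a ran from 0.10 to 0.69, miR-30c from 0.10 to 0.61 and miR-93 from −0.66 to −0.02. In the same way miR-92a ran from 0.05 to 0.49, miR-24 from −0.35 to 0.10 and let-7b from −0.52 to 0.13. Without control 1, miR-24-1* was at 0.33, and without control 4, let-7e was at −0.31. The means of the let-7, miR-17, miR-23 and adipocyte lists changed sign when single arrays were left out. With an estimated correlation 0 of the 12 lists passed. The miR-181, endothelial, liver and kidney, neural and epithelial lists had fewer than 3 tested members and were not tested.

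**Figure D3:**
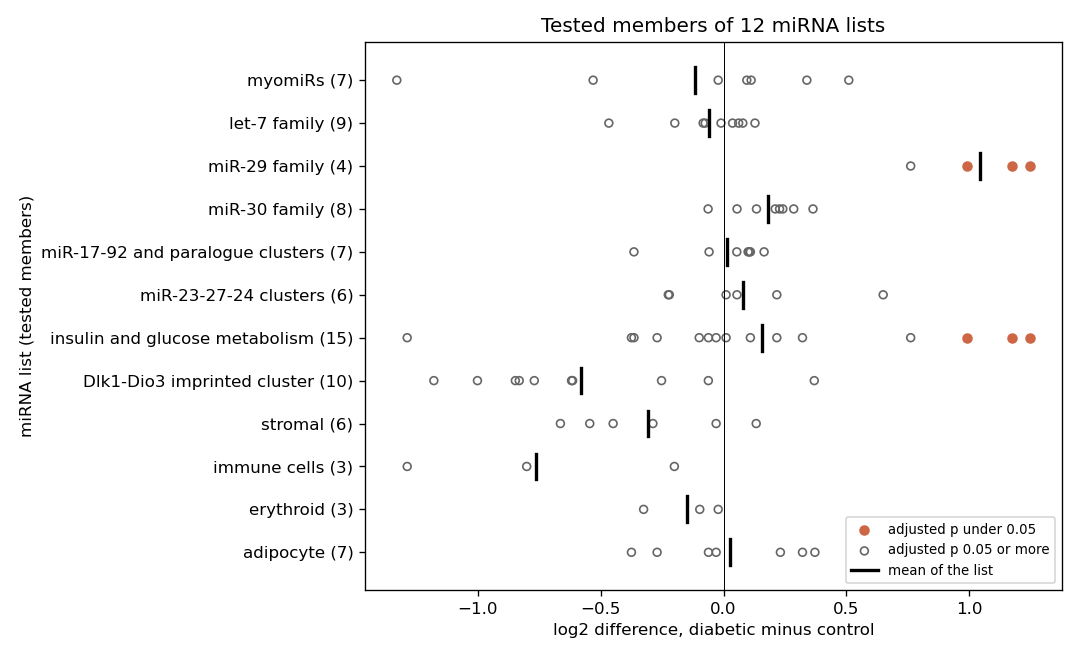
Log2 differences (diabetic minus control) of the tested members of 12 miRNA lists, with the number of tested members in brackets; filled points passed an adjusted p of 0.05 over all tested miRNAs, open points did not, and black bars are list means. The means run from −0.76 for immune cells to 1.04 for the miR-29 family.

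The control arrays varied more than the diabetic arrays. The median SD of a miRNA's log2 level was 0.43 over the 4 control arrays and 0.23 over the 4 diabetic arrays, and the control SD was the larger for 113 of the 126 miRNAs. Across miRNAs, which are not independent replicates, the correlation between 2 control arrays was 0.938 to 0.968 and between 2 diabetic arrays 0.971 to 0.988. The array labelled control 3 correlated at 0.970 to 0.985 with the diabetic arrays and at 0.955 to 0.968 with the other control arrays.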

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

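All tests of technical explanations in this part except the splits of the arrays were chosen after the results were seen, and so was the count of splits for the number of lists. The lists put to the splits were those that camera had called in these data.

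The first pattern is the rise of the miR-29 family on the arrays labelled diabetic. Of the 35 splits of the 8 arrays into 4 and 4, 1 (the real one) called at least 6 miRNAs, against at most 2 in any other. Again 1 (the real one) gave the family a camera p as small as 9.95e-08 with the preset correlation, against 0.000155 in the next. With an estimated correlation the family's camera adjusted p was 0.204. Being 1 of 35 is the smallest share this count can give, so for the number of calls chance is argued against but not excluded. The family had the smallest camera p of the 12 lists in the same data. Its share is not adjusted for that choice, so no conclusion about chance is drawn from it. A brightness or slide-row difference that scales all probes alike was divided out when each array was scaled, before the family was compared. The family's mean minus the array's median over tested miRNAs differed between groups by 1.01 (log2; two-sided exact permutation p = 0.0286, the smallest possible). That value restates the family's mean log2 difference of 1.04 on the scaled levels, so it is no separate test of such a difference. Cross-hybridisation among the mature family members as the whole cause is argued against by miR-29c*, which has another sequence and a lower 95% bound of 0.73, although its call was lost with normexp (log2 difference 0.38). For miR-29a and miR-29b it cannot be told apart from a rise of their own, since 0 of their other strands were tested. A slide-row effect on single probes also stays open, because 0 slide rows hold arrays of both groups, and so does the diabetic state as an untested biological explanation.

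The second pattern is the lower level of miR-223 and miR-342-3p on the diabetic arrays, where neither passed the threshold over all miRNAs and the difference of miR-223 was −0.70 without control 2, against −1.29 with it. Less whole blood in the diabetic samples would lower miR-451 as much. The within-array mean of the 2 miRNAs minus miR-451 differed between groups by −0.72 (log2; two-sided exact permutation p = 0.229), and the 95% interval of miR-451 ran from −1.09 to 0.44 (its difference was −0.33, or −0.048 without control 2), so less blood cannot be told apart from a change in leukocytes alone with these 8 arrays. Fewer leukocytes in diabetic muscle, as a biological explanation, was not tested.

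The third pattern is that the array labelled control 3 correlated better with the diabetic arrays than with the other control arrays. By a distance weighted with the spot noise (reduced chi-square), however, it lay nearest to control 4, at 47.9. That distance was 58.1 to 76.0 to the diabetic arrays, 134 to control 1 and 537 to control 2. On the 10 miRNAs called without it, its median position was 0.55 on a scale with the other control arrays at 0 and the diabetic arrays at 1 (quartiles 0.43 and 0.62), so a mislabelled diabetic array cannot be told apart from a control mouse in between. A swap of control 3 with 1 of the 4 diabetic arrays is argued against: the lowest correlation between 2 diabetic arrays, 0.971, exceeded the highest between a diabetic array and control 1, 2 or 4, 0.958, by 0.0132. Without control 3 the counts were 7 higher and 3 lower.

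For the Dlk1-Dio3 list, 8 of the 35 splits gave a camera p as small as the real 0.0016, and the smallest was 5.5e-07, so chance cannot be excluded; each of those 8 splits put control 1 and control 4 in the same group. At least 2 lists were called in 18 of the 35 splits, with 4 as the highest number, so the number of called lists does not stand apart from chance.

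Of 94 groups of 4 values examined for 1 array far from the other 3, 5 had one, and chance alone gives about 1 in 20. The miR-29c* level of control 2 was −4.87, against −4.40 to −4.33 on the other control arrays. The miR-206 level of diabetic 4 was −1.75, against −0.01 to 0.20 on the other diabetic arrays. The miR-410 level of diabetic 4 was −5.48, against −4.42 to −4.21. The miR-93 level of diabetic 1 was −4.996, against −5.58 to −5.55. The brightness of control 2 was 9.27, against 8.27 to 8.39 on the other control arrays.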

How the results depend on the processing

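By the sign of the log2 difference or of the list mean, no result changed direction while past its threshold in either setting. For the named miRNAs, 679 of 751 values kept their side of the threshold, 20 of them with a change of sign and no call in either setting, 45 lost a call and 27 gained one. Over all results 49 values changed sign without a call in either setting. miR-29c passed in 22 of 23 alternatives (log2 difference 1.12 to 1.57; adjusted p 0.000146 to 0.124) and miR-29c* in 21 of 23 (0.38 to 1.497). The other 4 calls held less often: miR-29b in 14 of 23 alternatives (0.81 to 1.31), miR-193 in 14 of 23 (0.79 to 1.49), miR-101a in 11 of 23 (0.65 to 1.35) and miR-101b in 10 of 22 (0.25 to 1.42). The higher count of 6 rose to 8 with the brightest probe or the percentile over all mouse probes and to 7 with the total gene signal, the mean of log2 over probes or miRNAs detected on all 8 arrays. It fell to 0 with no scaling, to 2 with no filter, where more miRNAs are tested, to 3 without control 2 and diabetic 4 together (chosen after seeing the data), and was 5 with quantile normalization, the median of the detected probes or normexp. Without each array in turn it was 2 to 7. The lower count of 0 became 1 with the percentile over all mouse probes, the total gene signal or array weights, 2 with quantile normalization, the median of the detected probes, the brightest probe or miRNAs detected on all 8 arrays, 3 with normexp, and 0 to 3 without each array in turn. The cause was not tested.

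With the replicate block 7 miRNAs were higher and 3 lower. The numbers showed no regular pairing of the samples: deviations of same-numbered arrays correlated at 0.21, 0.08, 0.51 and −0.29. These correlations were not tested, so a pairing is not excluded. Control 3 alone correlated best with its own number.

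The 2 called lists became 1 with quantile normalization or normexp, 5 with no filter, 0 with an estimated correlation, and 1 to 4 without each array in turn. With miRNAs detected on all 8 arrays 1 list was called, but there the Dlk1-Dio3 list had fewer than 3 tested members and was not tested. The miR-29 mean of 1.04 lost its call with an estimated correlation alone and ranged from 0.76 to 1.37 over its 4 tested members. It was 0.70 with no filter, where the mean is taken over all 6 members on the array. The Dlk1-Dio3 call ended at −0.29 with quantile normalization, −0.070 with normexp and −0.58 with an estimated correlation. Without filter the myomiR (mean −0.093), miR-30 (0.14) and insulin and glucose (0.066) lists gained a call. There each list holds all its members on the array and is compared with all 567 miRNAs, most of them not detected. The direction of camera was not recorded in that setting. For the myomiR list it was opposite to the sign of the mean in the main test, so −0.093 does not give the direction of its call. The list of the miR-17 cluster and its paralogues gained one at 0.19 without control 2 and diabetic 4 together. Without single arrays, the means of lists whose call changed ranged from −0.80 to −0.33 for Dlk1-Dio3 (call lost without diabetic 4, at −0.45), from −0.93 to −0.63 for immune cells (gained without control 4), from −0.097 to 0.22 for the miR-17 cluster and from 0.10 to 0.20 for insulin and glucose (both gained without control 2). The cause was not tested. Detected miRNAs and brightness kept their side of the threshold in every alternative. A block by slide was not run, since there is 1 slide. Signal over background limits the 441 untested miRNAs.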

Other observations

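The test on hairpin arms was chosen after the values were seen. miR-338-3p, named here after its value was seen, had a log2 difference of 1.41, above that of every miRNA that passed, with all 4 diabetic arrays above all 4 control arrays, but it did not pass (limma adjusted p = 0.0581). It passed in 8 of 23 alternatives, with differences from 0.86 to 1.73. miR-709 and miR-15b, also named after their values were seen, had log2 differences of −0.78 and −0.74 (limma adjusted p = 0.241 and 0.26). Neither passed in any of 23 alternatives, and without control 2 miR-15b was at −0.44. Of the members of the Dlk1-Dio3 list not named above, miR-127 was at −0.83, miR-337-5p at −0.85 and miR-154 at −0.77, and none of the 3 passed. They had 1, 2 and 1 of 8 values at the floor. Without control 4 miR-337-5p was at −0.46 and miR-154 at −0.495, and with normexp the 3 were at −0.051, −0.081 and −0.057.

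For 9 hairpins, matched by name, both arms were tested, and a shared change of the hairpin would move both arms alike. In the GRCm38.p6 gene table miR-24, miR-30c and miR-133a each have 2 hairpin genes. Their 2 arms need not come from the same hairpin, so this expectation need not hold for them. The log2 differences of the arms had the same sign in 6 of 9 hairpins, and their mean absolute difference was 0.29, against 0.53 over all 362880 pairings of arms (exact permutation p = 0.024). The relation rests on miR-29c, whose arms differed by 0.07: without it the exact permutation p was 0.205. The arms of miR-24, which has 2 hairpin genes, differed most, by 0.87, with miR-24 at −0.22 and miR-24-1* at 0.65.

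Of the 10 murine herpesvirus miRNAs on the array, 1, M1-2, was above background on all 8 arrays. Its mean intensity was 17.8 on the control arrays and 13.6 on the diabetic arrays, and the other 9 were detected on 0 arrays. Whether the M1-2 signal comes from a viral miRNA was not tested. A dim signal that counts as detected therefore need not show that the named miRNA was present.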
